A study of Drosophila melanogaster with 4 samples.

How the data were processed

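GAGA factor (GAF), a zinc-finger protein that binds GA-rich DNA and is encoded by the gene Trl, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos of Drosophila melanogaster aged 14 to 16 hours. The series holds 4 libraries, of which 2 are GAF ChIP replicates and 2 are inputs, that is, chromatin sequenced without immunoprecipitation. Replicate numbers follow the sample titles. Per the labels, the input numbered 1 served ChIP replicate 2 and the input numbered 2 served ChIP replicate 1, which crosses the numbers. This assignment rests on the labels alone and could not be tested here, since the inputs were not analysed.

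The analysis started from 3 deposited region lists, 1 for each ChIP replicate and 1 combined list for the replicate set. Per the file headers, coordinates are on FlyBase release 5 of the genome. The submitters' processing notes name the aligner Bowtie 0.12.7. The program that called the regions and its thresholds are not given in the sources used here, and neither is the way the replicates were combined. Each region has a type (significant enrichment or significant depletion), a start, an end and a score. The deposited score is signed: in all 3 lists it is above 0 in every enriched region and below 0 in every depleted region. The score is the authors' own value for each region. Its scale is not stated, so scores were compared by rank, by median or as differences in score units, and no fold change was taken from them. The files give no read counts, so sequencing depth is unknown, and the input libraries were not analysed here. The precision of a share of regions is given as an exact (Clopper-Pearson) 95% binomial interval, which covers counting error only and treats regions as independent.

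Enriched regions are called clusters below. Overlap meant at least 1 shared bp. Replicate lists were compared with 1000 random placements of the same widths on the same sequence, a one-sided permutation test of cluster positions whose smallest p is 0.000999. Scores were compared across clusters that overlapped 1 to 1. Combined clusters were sorted by whether a cluster of both, 1 or neither replicate overlapped them. The number of clusters on each of the 13 sequences that carried any was tested against the sequence's share of their summed length with an exact binomial test, adjusted by Benjamini-Hochberg over the 13 sequences. Uextra, a set of unplaced sequence in the header with no region in any list, was left out. Because neighbouring clusters are not independent, X against the autosomal arms and the centromere ends against the rest were also compared in bins of 1 Mb on the 5 large arms, with two-sided permutation tests of 100000 resamples over bins, adjusted over 16 tests. Bins shorter than 0.5 Mb were dropped, and the 2 bins nearest the centromere represented that end of each arm. The tests shuffled bins freely over arms and treated bins as independent, which neighbouring bins may not be. Clumping was measured as the variance-to-mean ratio of clusters in windows of 100 kb, against 1000 random placements.

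The routines were tested on simulated data, on the real sequence lengths except for the bin permutation, which used simulated bin counts. With 5080 simulated clusters, planted replicate overlaps of 30.5%, 60.3% and 89.5% were each recovered as planted. Planted clusters were kept identical and the others were placed clear of every cluster. This therefore checks only the counting of overlaps, not partial or chance overlap. An arm density raised 1.5 times was found in 100 of 100 simulations of 5694 clusters, and 5 of 100 simulations without a difference gave a call on any sequence. The bin permutation called 23 of 400 simulations without a difference. Both of these simulations drew counts independently, without the clumping seen in the real clusters. Their shares of false calls may therefore not hold for these data.

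The rule for what the text names was fixed before the data were examined, as were the tests and most of the alternatives; the bin tests, the centromere ends, the depleted regions and the bins of overlap by score were added after. The rule took the 15 highest-scoring combined clusters overlapped by both replicates and the 5 windows of 100 kb with the most clusters. Ties between windows were broken by summed score, a choice made after the counts were seen. The rule names genes only where a gene annotation of the same build is at hand. The gene table used here is of release 6, whose coordinates differ from those of release 5. No conversion between the releases was made, so no cluster was assigned to a gene. The planned results on promoters, genomic features, 21 fixed gene lists, sequence motifs, core promoter elements and score by place were therefore not computed, and clusters are named by position. Alternatives were a reciprocal overlap of 50%, clusters at or above the median score of their list, each replicate list alone, the clusters overlapped by both replicates, circular shifts in place of random placement, windows of 50 and 200 kb, and the 5 large arms alone. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.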

Results

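GAF occupancy was mapped in late embryos, at 14 to 16 hours, in 2 ChIP replicates. Replicate 1 had 5694 enriched clusters and replicate 2 had 5709, which is 5702 ± 10.6 (SD, n = 2). The clusters covered 15.3 Mb in replicate 1 and 15.4 Mb in replicate 2, or 11.0% and 11.1% of the 139.7 Mb of sequence that carried any cluster. The authors' combined list held 6474 clusters over 17.2 Mb, 12.3% of that sequence. The 5 large chromosome arms 2L, 2R, 3L, 3R and X held 6213 of the combined clusters. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

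The first question was how far the replicates found the same regions. GAF clusters recurred at the same places: 5254 of the 5694 clusters of replicate 1 (92.3%, interval 91.5 to 93.0%) overlapped a cluster of replicate 2, and 5233 of the 5709 clusters of replicate 2 (91.7%, interval 90.9 to 92.4%) overlapped one of replicate 1. Random placement gave 23.2% on average in both directions and at most 24.9% and 24.8%, so the observed overlap was 3.97 and 3.95 times the random one (one-sided permutation test of positions, p = 0.000999, the smallest that 1000 placements allow). Overlap followed the score. With each list divided into 4 equal groups by score, 1422 of the 1424 clusters in the highest group of replicate 1 were found again in replicate 2, and 1048 of 1424 in the lowest (73.6%, interval 71.2 to 75.9%). From replicate 2 to replicate 1 these were 1426 of 1427 in the highest group and 70.1% of 1428 (interval 67.6 to 72.5%) in the lowest. The 440 clusters in replicate 1 alone had a median score of 0.319 and the 476 in replicate 2 alone one of 0.329, against 1.46 and 1.53 for shared clusters.

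Scores also ranked alike. Over 5109 clusters paired 1 to 1, Spearman's rho was 0.958 (bootstrap interval 0.955 to 0.961) and Pearson's r was 0.969, both across clusters, which are not independent replicates. Replicate 2 scored higher at 58.0% of pairs, with a median difference of replicate 1 minus replicate 2 of -0.0434 against an SD of the differences of 0.279. The spread of 1 cluster's score between replicates was 0.199 (within-cluster SD, n = 2).

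**Figure D1:**
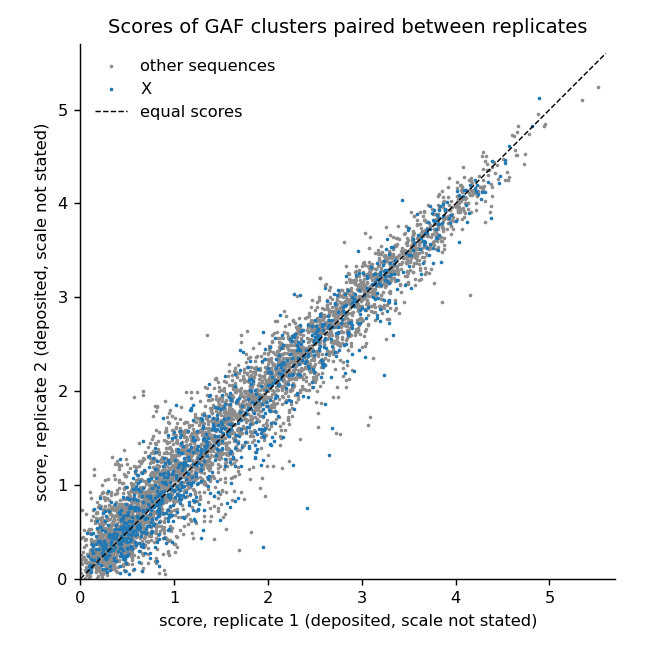
Each point is 1 of the 5109 clusters paired between replicates, with its score in replicate 1 on the x axis and in replicate 2 on the y axis (deposited scores, scale not stated); blue points lie on X and the dashed line marks equal scores. Points scatter about the line, with Spearman's rho of 0.958 and an SD of the differences of 0.279. Clusters without a 1 to 1 partner, among them those found in 1 replicate alone, are not shown.

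The strongest GAF cluster of the combined list lay on 3L from 14746843 to 14754601, with a score of 5.38 ± 0.19 over the replicates (mean ± SD, n = 2). The next lay on 3R from 8292248 to 8295279, at 5.23 ± 0.17. These means differed by less than the within-cluster SD of 0.199. A second strong cluster began within the same neighbourhood of 3R, from 8298868 to 8304963, at 4.90 ± 0.08. X carried a cluster from 16109639 to 16112803 at 5.01 ± 0.16, and another from 7192726 to 7197189 at 4.82 ± 0.01. On 2L, the cluster from 14489028 to 14492012 scored 4.91 ± 0.05, the one from 14408411 to 14412097 scored 4.66 ± 0.09 and the one from 12481856 to 12485603 scored 4.59 ± 0.10. The strongest cluster of 2R ran from 18128445 to 18132591 and scored 4.76 ± 0.04.

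Of these 15 strongest clusters, 6 were on 3R, 3 each on 2L and 3L, 2 on X and 1 on 2R. The others on 3R ran from 25596315 to 25601641 (4.88 ± 0.08), from 911304 to 914982 (4.71 ± 0.07), from 16077484 to 16081673 (4.67 ± 0.06) and from 5242271 to 5247538 (4.60 ± 0.05). The remaining 2 on 3L ran from 18763385 to 18766506 (4.74 ± 0.12) and from 21015438 to 21022213 (4.63 ± 0.15). Each of the 15 was matched by a single cluster in each replicate. All lay on the large arms.

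GAF clusters were typically about 2 kb wide, with a median of 2221 bp in replicate 1, 2231 bp in replicate 2 and 2201 bp in the combined list. A minority were much broader: 30 and 26 clusters of the replicates and 35 of the combined list spanned at least 10 kb. The widest combined cluster covered 22.1 kb of 2L from 16266510 to 16288625, where replicate 1 had 3 clusters and replicate 2 had 4. The second covered 19.5 kb of 3R from 27533801 to 27553348, where each replicate had 2 clusters. The third covered 18.1 kb of X from 2185797 to 2203921 and was 1 cluster in each replicate, with a score of 3.79 ± 0.05. A stretch of X from 3565116 to 3592168 held 2 neighbouring broad clusters of 12.8 and 14.2 kb, at 4.02 ± 0.18 and 3.86 ± 0.10. Wider clusters scored higher, with a Spearman's rho across clusters of 0.816 in replicate 1, 0.809 in replicate 2 and 0.794 in the combined list.

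**Figure D2:**
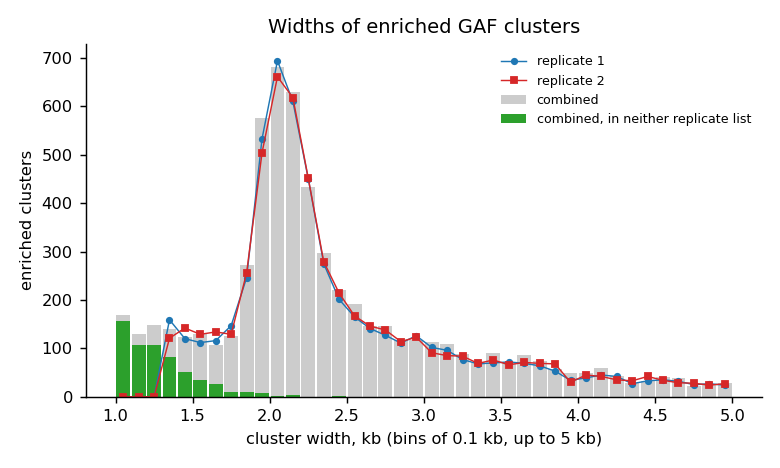
Number of enriched clusters (y axis) by width in bins of 0.1 kb up to 5 kb (x axis); grey bars are the combined list, green bars its clusters found in neither replicate list, and lines the 2 replicates. All 3 lists peak near 2 kb, and only the combined list has clusters under 1301 bp.

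The second question was what the combined list added. Both replicates had a cluster at 5150 of its 6474 clusters (79.5%, interval 78.5 to 80.5%), 1 replicate alone at 728 (11.2%), and neither at 596 (9.21%, interval 8.51 to 9.94%). Clusters shared by both replicates had a median score of 1.47 and a median width of 2363 bp. Those found in neither had a median score of 0.328 and a median width of 1226 bp, against a median score of 0.182 for those found in 1 replicate, and 370 of them were narrower than 1301 bp, the narrowest cluster of either replicate. Heterochromatin scaffolds and the unplaced sequence U held 12.4% of the clusters found in neither replicate, against 1.71% of those shared by both. In the other direction, 98.2% of replicate 1 clusters and 97.7% of replicate 2 clusters overlapped a combined cluster.

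The third question was how GAF clusters were spread over the chromosomes. X carried 59.0 combined clusters per Mb and 2R carried 56.2, which is 1.27 and 1.21 times the number expected from their lengths over all 13 sequences (exact binomial tests, adjusted p = 5.73e-20 and 3.5e-12). With the 5 large arms alone as the reference, the excess was smaller, at 1.13 times on X and 1.08 times on 2R (exact binomial tests, adjusted p = 3.3e-06 and 0.00838). 3R carried 51.5 and 3L 50.1 per Mb; they were 1.11 and 1.08 times the expected number (exact binomial tests, adjusted p = 1.64e-05 and 0.00384), but 0.987 and 0.960 times when the 5 large arms alone were the reference (adjusted p = 0.569 and 0.137). 2L, with 1035 clusters, was not distinguishable from expectation over all sequences (0.971 times, exact binomial test, adjusted p = 0.324) but lay below it among the 5 large arms (0.862 times, adjusted p = 3.04e-07). The small chromosome 4 had 59 clusters, 43.6 per Mb, and was not distinguishable from expectation at this number (exact binomial test, adjusted p = 0.703). The binomial tests here and in the next paragraph treat clusters as independent. Clusters were clumped (variance-to-mean ratio of 1.72 in windows of 100 kb on the 5 large arms), so these p-values are likely too small. Only X was also compared over bins, and the calls on the other arms rest on the binomial tests alone. In the replicates, density on X was 51.6 ± 1.26 per Mb, on 2R 50.8 ± 0.33, on 3R 46.3 ± 0.63, on 3L 45.2 ± 0.52, on 2L 39.5 ± 0.61 and on 4 38.1 ± 0.52 (mean ± SD, n = 2). The order of X and 2R differed between the replicates. X was denser in replicate 1 (52.5 against 50.6 per Mb) and 2R in replicate 2 (51.0 against 50.7).

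Assembled heterochromatin held few GAF clusters. The 6 heterochromatin scaffolds together had 12.9 combined clusters per Mb and 7.43 ± 0.15 per Mb in the replicates (n = 2), against 52.2 and 46.5 ± 0.20 on the large arms. 2RHet, 3LHet and 3RHet reached 0.269, 0.321 and 0.249 times expectation (adjusted p = 3.96e-26, 1.82e-17 and 1.28e-21, exact binomial tests). 2LHet had 7 clusters and YHet 1, also below expectation (exact binomial tests, adjusted p = 0.0135 and 7.37e-06); XHet, with 4 clusters against 9.46 expected, did not pass the threshold (adjusted p = 0.117). U reached 0.176 times expectation (exact binomial test, adjusted p = 1.25e-110). The replicate lists gave lower ratios, at 0.12 and 0.0828 on U, 0.164 in both on 2RHet, 0.221 and 0.211 on 3LHet, 0.166 and 0.175 on 3RHet, and 0.333 and 0.265 on 2LHet (replicate 1, then 2). The single combined cluster of YHet had no counterpart in either. Clusters on the heterochromatin scaffolds together scored lower too, with a median of 0.612 in replicate 1 and 0.634 in replicate 2, against 1.33 and 1.39 on the large arms. The medians on U were 1.11 and 1.25, nearer to those of the large arms. How much of the scaffolds and U could be aligned uniquely is not recorded.

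On average, the ends of the arms nearest the centromere also held fewer GAF clusters, though not on 3R. Here too, how much of the sequence could be aligned uniquely is not recorded. The 10 bins of 1 Mb at those ends averaged 37.2 ± 17.0 combined clusters per Mb, against 53.5 ± 12.4 in the other 109 bins (SD over bins; permutation test, p = 0.00027, adjusted p = 0.000709). In replicate 1 the averages were 29.4 and 47.9 per Mb and in replicate 2 they were 28.0 and 48.3 (permutation tests, adjusted p = 4e-05 for both). In the combined list the difference was large on 3L (20.3 against 52.0 per Mb), 2R (26.0 against 59.6) and X (39.5 against 61.5), small on 2L (42.5 against 45.2), and in the other direction on 3R (57.5 against 51.0). The replicates differed from it on these last 2 arms: 2L had 34.5 against 39.5 per Mb in replicate 1 and 33.0 against 40.6 in replicate 2, and 3R had 46.0 against 45.8 and 50.0 against 46.4. Scores at these ends were lower on all 5 arms, with a mean bin median of 0.701 against 1.16 in the combined list (permutation test, adjusted p = 0.000128). With 1 arm left out at a time, the density difference stayed between -22.3 and -12.3 clusters per Mb (permutation tests, highest p = 0.0128). All of these tests shuffled bins over the arms and did not pair each end with the rest of its own arm. Their p-values therefore describe bins, and no test over the 5 arms was run.

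In the same bins, X averaged 59.5 ± 13.0 combined clusters per Mb and the autosomal arms 50.5 ± 13.2 (22 and 97 bins; permutation test, p = 0.00455, adjusted p = 0.00662). Replicate 1 gave 53.1 against 44.8 (permutation test, adjusted p = 0.00662). Replicate 2 gave 51.2 against 45.6, which did not pass the threshold (permutation test, adjusted p = 0.0706) with all bins but did without the centromere ends (53.3 against 47.2, adjusted p = 0.030). Bin medians of the score were 1.03 on X and 1.14 on the autosomal arms, a difference that did not pass the threshold (permutation test, adjusted p = 0.184).

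**Figure D3:**
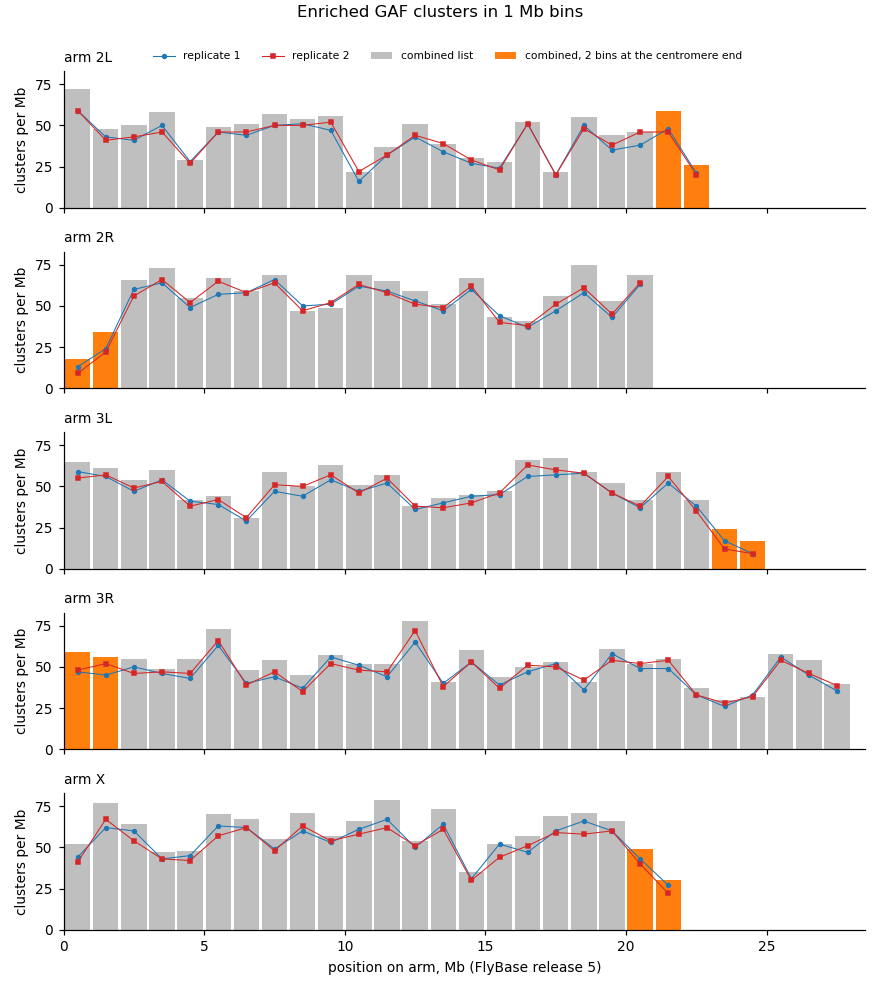
Clusters per Mb (y axis) in 1 Mb bins along the 5 large arms (x axis, FlyBase release 5); bars are the combined list, orange for the 2 bins at the centromere end, and lines are the 2 replicates. The centromere ends of 2R, 3L and X fall below the rest of their arms, and that of 3R does not.

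Clusters gathered unevenly along the genome. Over 1392 windows of 100 kb on all 13 sequences, heterochromatin scaffolds and U included, the variance-to-mean ratio of combined clusters was 2.16, against 1.48 in random placements (one-sided permutation test of positions, p = 0.000999, the smallest possible), and it was 2.07 and 2.20 in the replicates. Empty windows numbered 120, against 76.1 on average in random placements, and on the 5 large arms alone, a comparison chosen after the data were seen, 31 of 1189 against 7.01. The ratio there was 1.72, against 1.04 in random placements (permutation test of positions, one-sided p = 0.000999). Random placement used the full length of each sequence, including any that could not be aligned. It also took no account of the sparser centromere ends. The test therefore cannot separate these sources of unevenness from a gathering of GAF sites. The fullest window held 15 clusters, within the random range of up to 19. That window was X from 1100001 to 1200000, with 9 clusters in replicate 1 and 11 in replicate 2. X from 1900001 to 2000000 and 2L from 5000001 to 5100000 each held 14, with 13 and 12 in the first and 12 in each replicate in the second. 3R from 9800001 to 9900000 and 3L from 17900001 to 18000000 each held 13, as did 7 other windows. The 3R window had 15 clusters in replicate 1 and 13 in replicate 2, which equals the highest count of any window in each of these lists. The 3L window had 11 in each replicate. The fullest window of the combined list was therefore not the fullest in either replicate. By bins of 1 Mb, the densest were X from 11 to 12 Mb with 79 clusters, 3R from 12 to 13 Mb with 78 and X from 1 to 2 Mb with 77.

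Regions called depleted were few in the replicates, with 12 in replicate 1 and 8 in replicate 2, and numbered 210 in the combined list. Their combined scores ran from -0.194 to just below 0, with no strongly negative region, and their median width was 1761 bp.

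**Figure D4:**
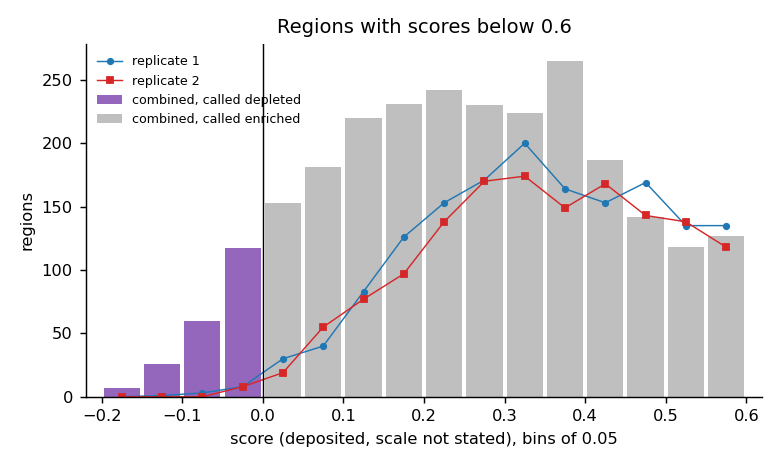
Number of regions (y axis) by score in bins of 0.05 below 0.6 (x axis, deposited scores, scale not stated); bars are the combined list, purple for regions called depleted and grey for clusters called enriched, and lines are the replicates. Numbers fall smoothly through 0, with 153 combined regions in the bin just above it and 117 in the bin just below.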

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

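The tests of explanations in this part were all chosen after the results were seen. Depleted regions stood out because the comparisons of enriched clusters do not use them: the combined list holds 210, replicate 1 holds 12 and replicate 2 holds 8.

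Of the 210 depleted regions of the combined list, 159 (75.7%) overlapped a cluster that a replicate list calls enriched, 21 of them in both replicates, 64 in replicate 1 alone and 74 in replicate 2 alone. Random placement gave 43.9 on average and at most 63, and placement that avoided the combined clusters gave at most 7. Conversely, of the 101 replicate 1 clusters missing from the combined enriched list, 83 lay on a combined depleted region, as did 95 of the 131 missing from replicate 2. The replicate scores at these places were low, with medians of 0.130 and 0.149, at the 2.14 and 2.61 percentiles of their lists. These medians cover all such places, and scores for the 21 regions enriched in both replicates were not taken apart. At those 21, the enriched calls of both replicates argue against a loss of signal below input, though calls with such low scores are weak evidence. At the 64 and 74 enriched in 1 replicate alone, the call argues against it in that replicate only, since the other's value is unknown. Weakly enriched regions whose combined score fell below 0 would give such low replicate scores. The replicates can differ in sign: 8 of the 12 depleted regions of replicate 1 lay on replicate 2 clusters (random placement at most 7). Of the 8 depleted regions of replicate 2, 3 lay on replicate 1 clusters (random placement at most 6). For the 51 regions on no replicate cluster a true loss stays open, since no read values are given.

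The 596 combined clusters found in neither replicate list are a second pattern. Of these, 370 (62.1%, exact interval 58.0 to 66.0%) were narrower than any replicate cluster, against 1.29% of the other combined clusters, so a lower width limit in the combined list is a candidate explanation for them, but not for the 226 that are wider. Greater depth of pooled reads reaching weaker regions would give lower scores than in clusters found in 1 replicate; the median was instead higher by 0.147 over all 596 (bootstrap interval 0.12 to 0.168) and by 0.192 over the 370 narrow ones (interval 0.173 to 0.209), but a width limit alone could keep narrow clusters out of the replicate lists, so these scores do not decide on depth. The wider 226 were tested apart only after the higher median over all 596 had been seen; their difference was 0.00214 (interval -0.0255 to 0.0427), so greater depth cannot be told apart from other causes for them either. No biological explanation was tested, since both replicates are of 1 group.

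The third pattern is a small difference between the replicates on X, which held, of the clusters found in 1 replicate alone, 114 in replicate 1 and 77 in replicate 2, while the 4 large autosomal arms held 293 and 382 (Fisher's exact test over clusters, two-sided p = 7.78e-05, odds ratio 1.93). The imbalance was not particular to X, since the unplaced sequence U held 19 and 4. Over 1 Mb bins, replicate 1 minus replicate 2 averaged -0.0156 on X and -0.0542 on the autosomal arms, a difference of 0.0386 in score units (two-sided permutation test, p = 0.00031, adjusted p = 0.000709), and 19 of the 22 X bins lay above the autosomal mean. An offset common to all clusters would move X and autosomes alike, so the difference argues against that as the whole cause. A different X dose in the chromatin or in the inputs, whose assignment rests on the labels, stays open, as 0 input libraries have values here, and so does a difference of scale between the lists; 2 libraries were compared, not conditions, and no biological explanation was tested.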

How the results depend on the processing

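Of 89 recomputed values, 73 kept their direction and side of the threshold, or stayed within their interval. Replicate overlap was 90.7% and 90.5% (replicate 1 in 2, then 2 in 1) with a reciprocal overlap of 50%, 93.5% and 93.2% between clusters at or above the median score, and 99.8% and 99.9% for those against the whole other list; the last was added after seeing the data. The rank correlation of replicate scores was 0.937 among clusters at or above the median score, whose range of scores is narrower. With the 5 large arms alone as reference, 3L and 3R moved below expectation (0.960 and 0.987 times) and 2L passed the threshold as low (0.862 times), by construction, since sparse heterochromatin then leaves the reference. 2L went from 0.971 to 1.01 times expectation among clusters at or above the median score, past the threshold in neither. XHet, with 4 clusters, passed the threshold among clusters at or above the median score (0 times expectation) and those overlapped by both replicates (0.266 times). With a replicate left out it ranged from 0.240, past the threshold, to 0.361. The bin and centromere tests and those of depleted regions were also chosen after. The excess of X over autosomes in bins ranged from 5.65 clusters per Mb without replicate 1, where it missed the threshold (p = 0.0573, permutation test), to 8.30 without replicate 2; the cause was not tested. Circular shifts keep the spacing of clusters, so the clumping ratio of 1.01 (permutation test by shifts, p = 0.199) under them says nothing about clumping. Replicate overlap cannot be computed with a replicate left out. The planned results that need a release 5 annotation or sequence were not run. No paired analysis was possible because the inputs enter only through the authors' region calls and no model across replicates was fitted. Depth is unknown, so weak clusters missing from 1 list cannot be called absent.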

Other observations

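The test on tied scores was chosen after a tied pair had been noticed, and the stretch of 2L was picked after its values were seen; the test on neighbours was chosen before its result was seen. On 2L from 21424049 to 21524965 the combined list had 11 clusters with a median score of 2.23, of which 7 overlapped no replicate cluster, and each replicate had 4. This stretch supplied 5 of the 10 highest-scoring clusters that neither replicate list holds, among them 21429127 to 21431124 with a score of 3.23, 21453257 to 21455257 with 3.04 and 21424049 to 21426194 with 3.01. Outside it, the highest was on 2R from 4378770 to 4379770, with 3.40. Of the 5 highest-scoring clusters found in replicate 1 alone, all were on U, the first from 8869887 to 8872018 with a score of 3.50. The highest found in replicate 2 alone was also on U, from 7288966 to 7290410 with 2.61.

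Some clusters within a list share exactly the same score. The combined list had 353 such clusters (5.45%), replicate 1 had 446 and replicate 2 had 480. A hypothesis is that these scores rest on few reads at repeated or poorly mappable sequence. In the combined list, 15.8% of clusters on the heterochromatin scaffolds and U had a tied score, against 5.12% elsewhere (Fisher's exact test over clusters, two-sided p = 3.26e-08), and 19.0% of the clusters found in neither replicate did, against 3.07% of those found in both. This is consistent with the hypothesis, but weak clusters in general may also rest on few reads, and neither mappability nor reads were measured.

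Another hypothesis was that strong clusters have more close neighbours than weak ones. In the combined list, 72.6% of the 1619 highest-scoring clusters and 71.0% of the rest had another cluster between 1 and 10 kb away. The difference of 1.66 percentage points lay within permutations that rotated the scores along each sequence (two-sided permutation test, p = 0.659, 1000 rotations). In the replicates the shares were 69.3% against 67.1% (permutation test, p = 0.249) and 70.2% against 68.1% (permutation test, p = 0.268). The test found no difference and does not exclude a small one.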
